A study of Mus musculus with 12 samples.

How the data were processed

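The samples were 12 ATAC-seq libraries of mouse tumour lines, 3 untreated and 3 treated with DAC for each of B16F10 (0.1 µM) and 4T1 (1 µM), with 48 h of treatment and removal of dead cells with magnetic beads, per the labels' protocols. Per the labels, nuclei were transposed with a Nextera kit, libraries were amplified and size-selected, and they were sequenced on either of 2 instrument types. Which library ran on which instrument is not given in the sources used here. MultiQC, FastQC, Bowtie2, Picard, MACS2, DiffBind and ChIPseeker and the genome build mm10 are named in the submitters' processing notes, without versions, options or roles.

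The files used were 1 peak list per library in the narrowPeak layout. The fold enrichment of each peak, a ratio to the local background of the same library, was made by the authors' peak caller. The deposited −log10 p-value and −log10 q-value are those of each peak within its own library and grow with depth. The deposited score equals 10 times the −log10 q-value without its decimals. The position of the summit within the interval is also the authors'. Every list ended at a q of 0.05, held 1 summit per interval and no mitochondrial peak, and was called on its own library. The lists hold no read counts, so that no counting interval could be given, and the background read density under the peaks was recovered for each library from pairs of fold enrichment and p-value, taken as Poisson probabilities with 1 added to pileup and background. It was 4.19 ± 0.215 in untreated and 5.89 ± 0.613 in treated 4T1 libraries and 1.75 ± 0.0749 and 1.75 ± 0.219 in B16F10 (SD, n = 3). Within a library the pairs differed in this density by at most 0.185 in B16F10 and 2.4e-05 in 4T1, so it is less exact in B16F10.

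Distinct intervals on the 21 assembled chromosomes were kept. Peaks of the 6 libraries of a line were merged into regions where they overlapped by at least 1 bp, and a library called a region when it had a peak in it. A region or promoter is called in DAC libraries alone when 3 of 3 DAC libraries and 0 of 3 controls called it, and in controls alone for the reverse. The sequence was GRCm38, the assembly that mm10 names, and genes were taken from GENCODE release M21. Promoters were the 5′ end of each protein-coding gene plus and minus 1000 bp, and 7 list genes of other types were kept, for 21918 genes. CpG density, island-like content (CpG observed to expected above 0.6 with GC above 50.0%) and soft-masked repeat bases were measured over whole peaks, and 17 consensus motifs were sought on both strands in the 200 bp around the strongest summit.

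A set of 17 gene lists was written before the data were examined, as were the tests, the main settings and most alternatives. The lists held germline and cancer-testis genes, antigen presentation, interferon response and nucleic acid sensing, chemokines, immune checkpoint and NK ligands, imprinted genes, tumour suppressors, pyroptosis and inflammasome, p53 targets and DNA damage, DNA methylation machinery, markers of melanocytes, mammary epithelium, leukocytes, fibroblasts and endothelium, neurons and hepatocytes, and housekeeping genes. Of their 507 symbols, 504 matched the annotation directly and 3 through an older symbol, giving 499 distinct genes. Genes named in the text are, per line, list members called in 1 arm alone (at most 25, by rank), the 10 genes of highest rank per direction, up to 15 genes called in the same arm alone in both lines, and 8 genes fixed in advance. A gene that this rule names is not reported here. The rank is the lowest of the 3 libraries' percentiles of −log10 q. The 5 regions of highest rank per direction are named with coordinates counted from 1.

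Values per library were compared by exact two-sided permutation of the treatment labels, within a line (20 relabellings, smallest p 0.10) and over both lines with labels permuted within each line (400 relabellings, smallest p 0.005), with Benjamini-Hochberg adjustment over 25 measures or 17 lists. The difference between the lines was tested with the same relabellings, a test of no effect in either line that hardly reaches a small p where both lines move in the same direction. Regions, promoters and lists were compared by Fisher's exact test, lists against the other genes that could have passed (those without a control call for DAC-alone genes). Regions and genes are not independent replicates in these tests. Counts were set beside those of the 10 splits of the 6 libraries of a line. Primer binding sites were 18-base sequences complementary to the 3′ ends of tRNA genes that the annotation lists at least 2 times, with the added CCA. Alternatives were a stricter q, fold enrichment of at least 5, equal numbers of peaks (49622 in B16F10 and 89780 in 4T1), 2 of 3 libraries, other overlaps and promoter widths, every transcript start, whole-peak motifs, summit CpG, a replicate block, every deposited line and each library left out. Those added after the data were seen are named with the effects of the settings.

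The work ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, with random seed 20. The calls were tested on simulated peak lists in which 200 regions per direction and line were set to be called in every library of 1 arm and none of the other. Of these, 199 and 199 were recovered among 79494 regions in B16F10 and 198 and 198 among 146901 in 4T1, with 0 in the wrong direction. Since the set regions met the rule exactly, this tests the merging of peaks. It does not measure how often calls drop out or how many unchanged regions pass. Of 1000 random lists of 60 genes, 2.9% passed in B16F10 and 4.6% in 4T1, and of 1000 unchanged data sets 3.7% passed the test over both lines. Peaks on unplaced and patch sequences were left out of the comparisons, since the annotation used covers the assembled chromosomes.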

Results

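Accessible chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in 2 mouse tumour lines. B16F10 is a melanoma line and 4T1 is a mammary carcinoma line. Each line was left untreated or treated for 48 h with decitabine (DAC), a nucleoside that is built into DNA and traps DNA methyltransferases, at 0.1 µM in B16F10 and at 1 µM in 4T1. The 4 groups held 3 libraries each, 12 in all, and dead cells had been removed before transposition. The labels speak of replicates and triplicates but nothing in them says that these came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical. The authors called peaks in each library on its own. The lists carried between 50126 and 119795 peaks per library, of which 49622 to 118603 lay on the 19 autosomes, X and Y. Read totals were not among the values used, so the depth of each library is unknown beyond the minimum that the labels give. The score and the fold enrichment of each peak are the authors' and served here only to describe, rank or filter peaks within their own list. A peak's strength percentile is the rank of its −log10 q within its own library, and for a region or promoter the lowest of the 3 libraries is given.

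The first comparison asked how far DAC changed the amount of open chromatin in each line. Treated 4T1 cells had 112440 ± 5488 peaks (SD, n = 3) against 92033 ± 2225 in untreated cells, a ratio of 1.22. Treated B16F10 cells had 55540 ± 2536 peaks against 52072 ± 2122, a ratio of 1.07. The B16F10 difference of 3469 became 2005 without DAC replicate 2 and 2244 without control replicate 2. How the gain in 4T1 was spread over strong and weak peaks depended on the measure of strength. At a −log10 q of at least 5, which grows with depth, 98847 ± 4971 peaks stood against 86135 ± 1593 in 4T1 and 47076 ± 2820 against 45602 ± 1728 in B16F10 (exact permutation over both lines, two-sided, p = 0.03; B16F10 alone, p = 0.6). Peaks with a fold enrichment of at least 10, a ratio to the background, were fewer after DAC in both lines, with 28094 ± 303.3 against 36795 ± 352.3 in 4T1 and 18038 ± 914.3 against 20792 ± 595 in B16F10 (exact permutation over both lines, two-sided, p = 0.005). Within a line an exact two-sided permutation test of 3 against 3 libraries cannot go below p = 0.10, and both lines gave that value for all peaks. With treatment relabelled within each line, the mean difference of 11938 peaks gave p = 0.005 in the exact two-sided permutation test, the smallest p possible, and 0.0208 after Benjamini-Hochberg adjustment over 25 measures. Among peaks of fold enrichment of at least 5 the 4T1 count fell by 3017 and the test over both lines gave p = 0.15 (exact permutation, two-sided). The B16F10 count rose by 378 in that setting (exact permutation, p = 0.7).

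**Figure D1:**
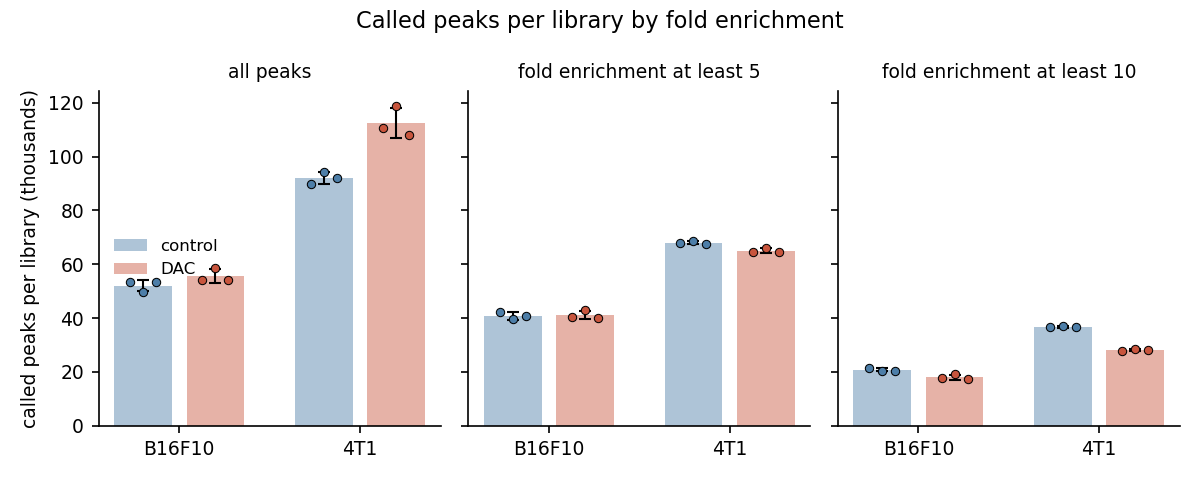
Called peaks per library (vertical axis, in units of 1000) in control and DAC libraries of B16F10 and 4T1, for all peaks and for peaks of fold enrichment of at least 5 and at least 10; bars are means, error bars are SD and points are the 3 libraries. The order of the 4T1 groups changes from 92033 below 112440 for all peaks to 36795 above 28094 at a fold enrichment of at least 10.

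Peaks covered 59.3 ± 2.30 Mb of the genome in treated and 53.7 ± 0.928 Mb in untreated 4T1 cells, and 33.6 ± 1.97 against 32.3 ± 1.44 Mb in B16F10 (n = 3 each). The difference of 1.28 Mb in B16F10 became 0.165 Mb without DAC replicate 2 and 0.467 Mb without control replicate 2. The mean difference of 3.45 Mb gave p = 0.03 in the exact two-sided permutation test over both lines and an adjusted p of 0.0536. That difference was 0.446 Mb with the same number of peaks per library (exact permutation, p = 0.4). It turned to −0.662 Mb at a fold enrichment of at least 5 (exact permutation, p = 0.345). The share of peaks at promoters, within 1000 bp of the 5′ end of a protein-coding gene, was lower by 0.918 percentage points on average, with 12.1 ± 0.388% against 13.01 ± 0.266% in 4T1 and 18.4 ± 0.655% against 19.3 ± 0.729% in B16F10 (exact permutation over both lines, p = 0.005, adjusted p = 0.0208). That direction turned when every library of a line was limited to the same number of peaks, which gave a promoter share higher by 0.217 percentage points after DAC (exact permutation, p = 0.025). Libraries of the same arm shared more of their peak bases than libraries of different arms, with mean Jaccard indices of 0.782 ± 0.0305 (SD over 6 pairs) and 0.609 ± 0.00138 (9 pairs) in 4T1, and 0.692 ± 0.0200 and 0.654 ± 0.00255 in B16F10. The difference within the lines averaged 0.106 (one-sided exact permutation over the 100 combinations of splits, p = 0.01, the smallest possible).

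In treated 4T1 cells, peaks appeared in CpG-rich and repeat-rich sequence. Of 146901 regions called in at least 1 of the 6 libraries, where peaks overlapping by at least 1 bp were merged, 67077 were called in all 6 libraries, 17630 in the 3 DAC libraries and no control, and 5249 in the 3 controls and no DAC library. Their median strength percentiles were 56 (lowest of the 6 libraries), 28.4 and 15.1, so comparisons with regions called in all 6 also set weaker peaks against stronger ones. The regions called in DAC libraries alone had a median of 3.13 CpG per 100 bp, against 0.912 in the regions called in controls alone and 1.42 in those called in all 6 libraries. CpG content typical of islands was present in 31.0% of them against 0.781% of the control-alone regions (odds ratio 57.1) and 14.97% of those called in all 6 libraries (odds ratio 2.56). Of the DAC-alone regions 47.1%, and of the control-alone ones 6.97%, consisted mostly of annotated repeats (odds ratio 11.9). They lay between genes in 49.6% of cases and at promoters in 5.27%, against 38.9% and 2.00% of the control-alone regions (promoters, Fisher's exact test, p = 2.2e-27). Regions called in all 6 libraries lay at promoters more often, in 15.5% of cases (odds ratio 0.303 for the DAC-alone regions).

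Their sequences also differed at transcription factor motifs. The cAMP response element (CRE), bound by CREB and ATF proteins, lay near the summit of 14.2% of the DAC-alone regions of 4T1 and of 0.210% of the control-alone regions (odds ratio 79.0, Fisher's exact test, adjusted p = 1.2e-279). Most of this CRE signal came from regions that carry a single repeated 16-base sequence. Without them, CRE lay in 1.77% and NFY in 12.5% of the DAC-alone regions, against 1.07% and 4.12% of those called in all 6 libraries. The CCAAT box bound by NFY was present in 29.2% against 2.44% (odds ratio 16.5), and the SOX motif in 4.82% against 1.05% (Fisher's exact test, adjusted p = 1.2e-43). Motifs of AP-1 (15.1% against 28.3%, Fisher's exact test, adjusted p = 1.7e-96), TEAD (12.6% against 19.9%, adjusted p = 1.7e-37), RUNX (1.06% against 4.71%, adjusted p = 3.4e-53) and CTCF (0.766% against 2.31%, adjusted p = 1.9e-17) were less frequent in the DAC-alone regions. The regions with the 16-base sequence carried almost none of these motifs. Without them the DAC-alone shares were 18.91% for AP-1, 15.75% for TEAD, 1.33% for RUNX and 0.955% for CTCF. Each stayed below its control-alone share. In regions called in all 6 libraries the shares were 34.76%, 15.85%, 2.99% and 5.19%, so TEAD was nearly equal there. Of 17 motifs, 13 passed an adjusted p of 0.05 in this comparison of regions, which are not independent replicates. Per library, CRE lay in 3.09 ± 0.0876% of peaks of treated and 0.827 ± 0.0110% of untreated 4T1 cells, and NFY in 8.33 ± 0.102% and 3.72 ± 0.0299% (n = 3 each). In B16F10 the CRE shares were 0.829% and 0.802%, and over both lines CRE gave p = 0.01 (adjusted p = 0.0313) and NFY p = 0.025 (adjusted p = 0.0521) in exact two-sided permutation tests.

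**Figure D2:**
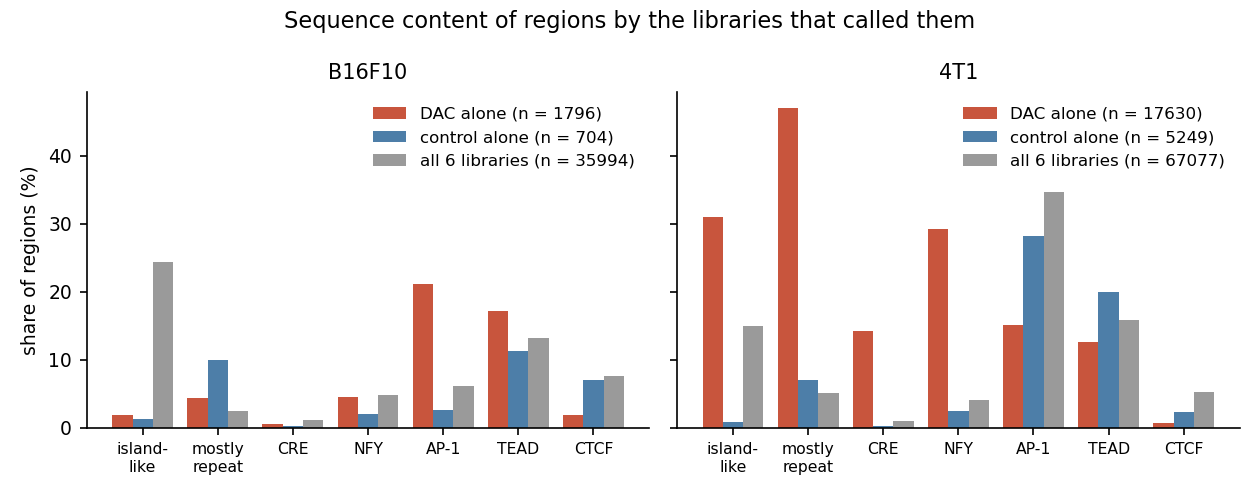
Share of regions (vertical axis, %) with island-like CpG content, with mostly repeat sequence, or with each of 5 motifs near the summit, for regions called in the 3 DAC libraries alone, in the 3 controls alone or in all 6 libraries of B16F10 and 4T1. In 4T1 the DAC-alone bars are highest for repeats, at 47.1%, and in B16F10 the tallest DAC-alone bar is that of AP-1, at 21.2%.

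The 5 DAC-alone regions of 4T1 with the highest strength percentile lay in an intron of Mapk10, which encodes the kinase JNK3 (chromosome 5, 103026710 to 103027434, mm10, percentile 99.2) and in an intron of Zfp532 that overlaps an antisense exon (chromosome 18, 65622493 to 65623092, 97.1), and others at the promoters of Hs3st1, a heparan sulfate sulfotransferase gene (chromosome 5, 39755305 to 39756091, 95.4), and Stpg2 (chromosome 3, 139205340 to 139206173, 95.2), and between genes in a stretch made up fully of repeat sequence (chromosome 3, 22730174 to 22732181, 94.6). The 5 control-alone regions of highest rank in the control lists lay in introns of Pdlim2 (chromosome 14, 70169244 to 70169691, with an AP-1 motif, percentile 73.4), Anapc1 (chromosome 2, 128658301 to 128658758, 68.8), Entpd3 (chromosome 9, 120545227 to 120545999, 66.4) and Chd7 (chromosome 4, 8795579 to 8796420, 65.6), and at the promoter of Def8 (chromosome 8, 123422239 to 123422880, with a CTCF motif, 66.1). Limited to the same number of peaks per library, 4T1 had 11593 DAC-alone and 8909 control-alone regions, and at a fold enrichment of at least 5 it had 8074 and 8121.

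At 4T1 promoters, genes of the germline stood out among those with a peak after DAC alone. Of the 63 germline and cancer-testis genes in the list, 36, 39 and 34 had a promoter peak in the 3 treated libraries against 3 in each control. They include the germ cell RNA-binding protein gene Dazl, the germ cell helicase gene Ddx4, the meiotic cohesin gene Stag3, the meiotic chromosome genes Sycp1, Syce1, Hormad1 and Meiob, the piRNA pathway genes Mov10l1, Piwil2, Asz1 and Gtsf1, and the testis bromodomain gene Brdt. All of these were called in 3 of 3 DAC libraries and no control, with strength percentiles of 84.7 for Stag3, 80.9 for Brdt, 76.3 for Mov10l1, 72.9 for Dazl and 47.0 for Ddx4. At Dazl the 3 peaks spanned from 50292660 at the lowest to 50293870 at the highest position on chromosome 17 and covered the 5′ end of the gene at 50293636. For Brdt and Gtsf1 another annotated transcript start had a peak in every control.

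**Figure D3:**
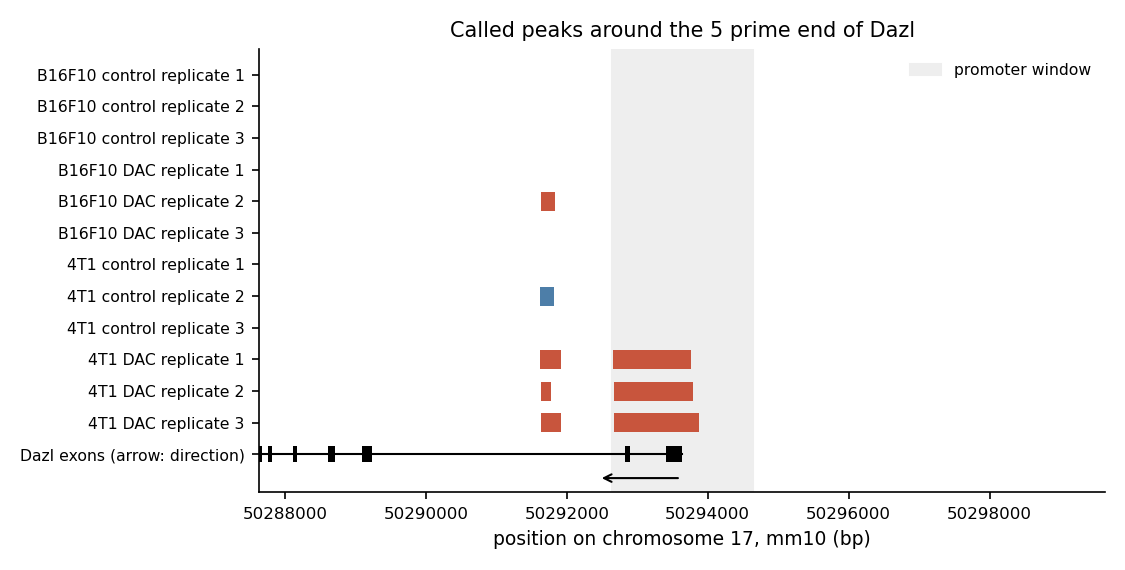
Called peaks (bars, one line per library) around the 5′ end of Dazl on chromosome 17 (horizontal axis, mm10 position in bp), with the exons in black and the promoter window in grey. Inside the window, peaks stand in the 3 DAC libraries of 4T1 alone, from 50292660 to 50293870, and small peaks near 50291620 lie outside it.

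Of the 60 germline genes without a call in any 4T1 control, 30 were called in all 3 DAC libraries, against 895 of 9260 other genes without a control call (odds ratio 9.35, Fisher's exact test, adjusted p = 5.5e-14 over 17 lists). Set against genes of similar promoter CpG density, a comparison chosen after the values were seen, the odds ratio was 9.15 and 10.0 members were expected (permutation test with 100000 draws, p = 1.0e-05, the smallest possible, adjusted p = 1.7e-04). Among imprinted genes, 12 of 26 were called in DAC libraries alone, in 10 distinct promoter regions, among them Peg3 and Usp29, which share a region, and Zrsr1 (odds ratio 7.87, Fisher's exact test, adjusted p = 1.9e-05). Matched for CpG density, their odds ratio was 2.39 and the adjusted p was 0.458 (permutation test). The neuronal genes Gad1, Gad2, Grin1, Nefl and Nefm made 5 of 12 (Fisher's exact test, adjusted p = 0.0236). Matched for CpG density, their odds ratio was 1.301 and the adjusted p was 1 (permutation test).

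The immune and tumour suppressor lists gave smaller counts in 4T1. The interferon-induced genes Ifi44 and Oas2 made 2 of the 3 members of the interferon and nucleic acid sensing list that lacked a control call (odds ratio 18.2, Fisher's exact test, adjusted p = 0.117). That list passed with promoters of plus and minus 500 bp (3 members, adjusted p = 0.0266), without control replicate 2 (adjusted p = 0.038) and when matched for CpG density (adjusted p = 0.00527, permutation test). The chemokine genes Cxcl12, Cxcl14 and Ccl4 made 3 of 10 (Fisher's exact test, adjusted p = 0.234). Raet1e and H60b, which encode ligands of a natural killer cell receptor and share 1 promoter region, made 2 of 9 of the checkpoint and NK ligand list (Fisher's exact test, adjusted p = 0.509). Another transcript start of Raet1e had a peak in every control. Of the tumour suppressors, 5 of 24 were called in DAC libraries alone, namely the Wnt antagonist gene Sfrp5, Cdkn1c, Gata5, Igfbp3 and Zmynd10 (Fisher's exact test, adjusted p = 0.234). The necroptosis kinase gene Ripk3 was 1 of 11 in the pyroptosis and inflammasome list and Pmaip1 was 1 of 3 p53 targets (Fisher's exact test, adjusted p = 1 and 0.509). Pax3 and Kit were 2 of 16 melanocyte genes and Twist2 was 1 of 16 fibroblast and endothelial genes (Fisher's exact test, adjusted p = 1 each). None was called in DAC libraries alone among antigen presentation genes (0 of 1), DNA methylation machinery genes (0 of 7), mammary epithelial genes (0 of 2), hepatocyte genes (0 of 16), leukocyte genes (0 of 19, Fisher's exact test, adjusted p = 0.509) and housekeeping genes (0 of 1). The leukocyte transcription factor gene Spi1 was the member of a list called in the 4T1 controls alone (1 of 4, Fisher's exact test, adjusted p = 0.509). Members of lists named here beyond the 25 of highest rank were chosen after their values were seen.

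**Figure D4:**
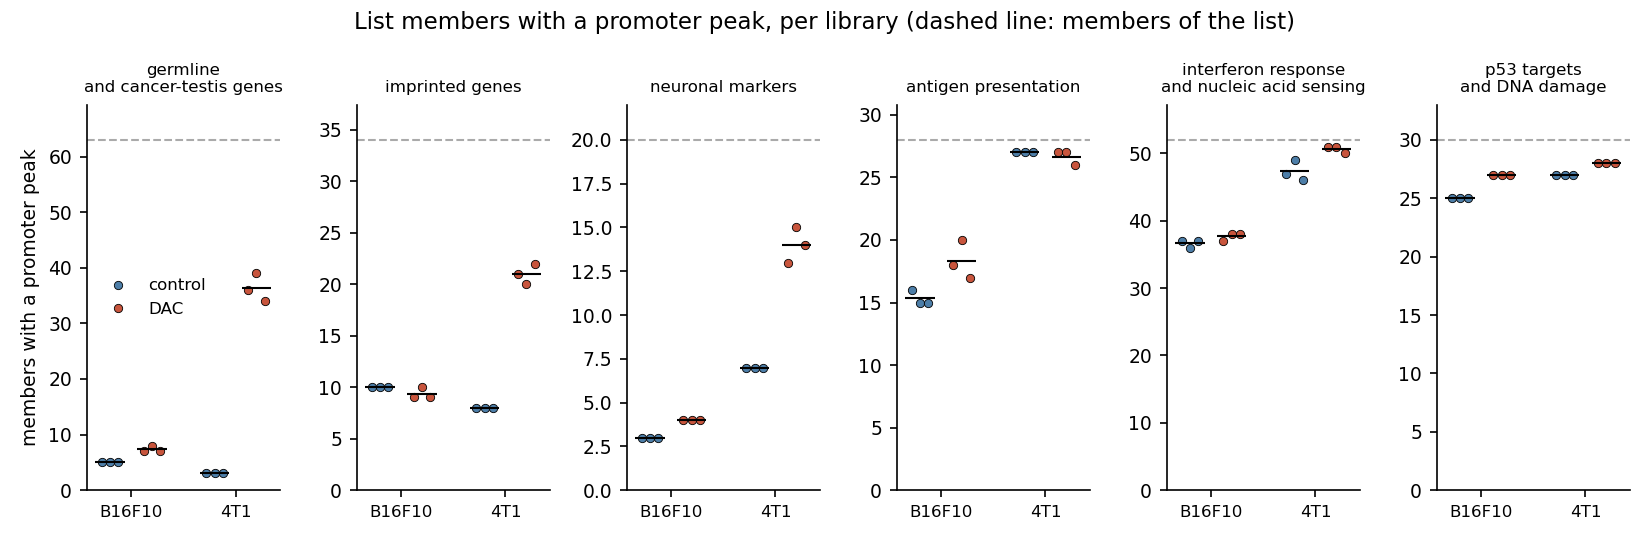
Members of 6 gene lists with a promoter peak (vertical axes, number of genes) in each control and DAC library of B16F10 and 4T1; points are libraries, horizontal lines are group means and the dashed line is the size of the list. Germline genes go from 3 in each 4T1 control to 34 to 39 in the 4T1 DAC libraries, and antigen presentation genes stay at 26 or 27 in 4T1.

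In all, 925 genes of 21918 had a promoter peak in the 3 DAC libraries of 4T1 and no control, and 92 had the reverse. Promoters of high CpG density were called so most often. Of the 584 genes in the highest of 5 equal groups by CpG density that lacked a control call, 389 (66.6%) were called in DAC libraries alone, against 536 of 8736 (6.14%) in the other groups (odds ratio 30.5, Fisher's exact test, p = 1.9e-274). The genes of highest rank were Hs3st1, Stpg2, 3110070M22Rik and Tmem267 (1 shared region, percentile 90.6), Tmeff2 (87.4), Aebp1 (85.7), Gpat2, an acyltransferase gene (85.3), Hrasls5 (84.7), and Gm43720 and Gpc2, which share the region of Stag3. Aebp1 lay in a merged region called in all 6 libraries, and at Hs3st1 another transcript start had a peak in every control. Limited to the same number of peaks per library, the counts were 487 and 175, and at a fold enrichment of at least 5 they were 249 and 248.

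**Figure D5:**
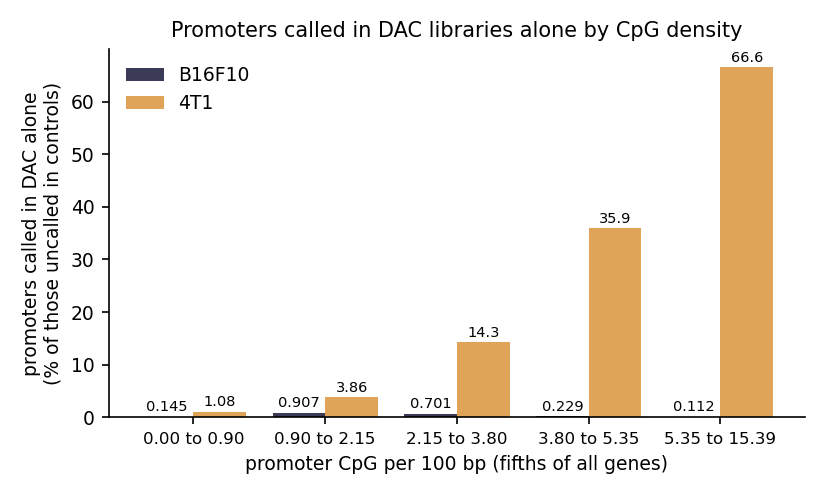
Share of promoters called in the 3 DAC libraries alone (vertical axis, % of promoters that lack a control call) in 5 equal groups of genes by promoter CpG per 100 bp (horizontal axis), for B16F10 and 4T1. The 4T1 share climbs from 1.08% to 66.6%, and the B16F10 share stays below 1% in every group.

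The 10 genes of highest rank called in the 4T1 controls alone were Fdft1, which encodes squalene synthase, Zscan10, Pdpk1, Hnrnpm, Gng3, Ifitm6, Def8, Fgl1, Pik3ip1 and C1qtnf1, with percentiles from 96.6 for Fdft1 to 50.4 for C1qtnf1. For 7 of them (Fdft1, Zscan10, Pdpk1, Hnrnpm, Gng3, Ifitm6 and Fgl1) the peak belonged to a merged region that all 6 libraries called, so the libraries differed in whether the peak's edge entered the promoter window. Def8, Pik3ip1 and C1qtnf1 lay at regions without a DAC call. Another annotated transcript start had a peak in every DAC library for 8 of the 10, all but Gng3 and Fgl1.

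In B16F10, fewer regions had a peak after DAC alone, and many of these carried an AP-1 motif while few had island-like CpG content. Of 79494 regions, 35994 were called in all 6 libraries, 1796 in DAC libraries alone and 704 in controls alone. The median strength percentile was 15.3 in the DAC-alone and 13.45 in the control-alone regions. In regions called in all 6 libraries it was 58.4 (lowest of the 6), so comparisons with these also set weak peaks against strong ones. AP-1 sites lay near the summit of 380 of the DAC-alone regions (21.2%) against 18 of the control-alone regions (2.56%; odds ratio 10.2, Fisher's exact test, adjusted p = 2.5e-37). Motifs of TEAD (17.2% against 11.4%, Fisher's exact test, adjusted p = 0.0016), NFY (4.45% against 1.99%, adjusted p = 0.0137) and the E-box CACGTG bound by MITF and MYC (5.29% against 2.84%, adjusted p = 0.0265) were also more frequent. CTCF sites were less so (1.95% against 6.96%, Fisher's exact test, odds ratio 0.266, adjusted p = 3.5e-08). These 5 of the 17 motifs passed the threshold. Against the regions called in all 6 libraries, AP-1 (6.15% of those, odds ratio 4.10), TEAD and CTCF kept their direction and passed, while the E-box (5.02%, adjusted p = 0.619) and NFY (4.82%, adjusted p = 0.567) did not pass in Fisher's exact test. Island-like CpG content was present in 1.84% of the DAC-alone and 1.28% of the control-alone regions (Fisher's exact test, adjusted p = 0.519), and mostly repeat sequence in 4.40% and 9.94% (adjusted p = 1.9e-06). In regions called in all 6 libraries the share of mostly repeat sequence was lower, at 2.54% (odds ratio 1.77, Fisher's exact test, adjusted p = 1.3e-05). Island-like content was far more frequent there, at 24.4% (odds ratio 0.0579 for the DAC-alone regions, Fisher's exact test, adjusted p = 7.1e-159). Per library, AP-1 sites lay in 7.60 ± 0.0750% of peaks of treated and 5.60 ± 0.117% of untreated B16F10 cells (n = 3 each).

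The 5 DAC-alone regions of highest rank in B16F10 lay in an intron of the long non-coding RNA gene Gm19951 near Foxn3 (chromosome 12, 99645130 to 99645675, percentile 69.0), in the untranslated region of Fbxw7, a ubiquitin ligase subunit gene (chromosome 3, 84951867 to 84952659, 67.7), in introns of Cep131 (chromosome 11, 120073333 to 120073625, with a CTCF motif, 67.3) and Copg1 (chromosome 6, 87897907 to 87898354, with an AP-1 motif, 62.4), and between genes near Zfp622 (chromosome 15, 26051222 to 26051961, with an AP-1 motif, 62.7). The control-alone regions of highest rank lay near Odf3l2 (chromosome 10, 79649333 to 79649859, 62.4), in an exon of the cyclin gene Ccnd2 (chromosome 6, 127147809 to 127148147, with a CTCF motif, 60.8), and in introns of Tango2 (chromosome 16, 18345307 to 18345534, 60.2), Myh14 (chromosome 7, 44655469 to 44655902, 59.2) and Fgfr2 and Tacc2, which overlap (chromosome 7, 130670243 to 130670637, 58.01).

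Promoters called in DAC libraries alone numbered 50 in B16F10 and included the p53 targets Fas, a death receptor gene, and Cdkn1a, which encodes the cell cycle inhibitor p21. These made 2 of the 5 p53 targets without a control call (odds ratio 149, Fisher's exact test, adjusted p = 0.00356). When every annotated transcript start counted as a promoter, the list held 1 such gene and the adjusted p was 0.436, because another transcript start of Cdkn1a had a peak in all 12 libraries. Counted per library, 27 of the 30 p53 targets had a promoter peak in each treated and 25 in each untreated B16F10 library, and 28 and 27 in 4T1 (exact permutation over both lines, two-sided, p = 0.005, adjusted p = 0.0283). Promoter calls over all genes were also higher in the treated libraries of both lines, and this count was not set against them. The other DAC-alone genes of highest rank were Pdgfa, a growth factor gene (percentile 67.0), the germline gene Tex19.1 (48.6), Gstp2 (44.1), Cul4b (43.7), Xlr3c (43.6), Acap1 (40.6), Usp7 (39.7) and Trim12c (39.4). Fas had a percentile of 40.2 and Cdkn1a of 39.7. Of these 10 genes, Tex19.1, Xlr3c, Fas and Trim12c lacked a control call at every annotated transcript start, and Pdgfa lay in a merged region called in all 6 libraries.

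The other lists gave few calls in B16F10. Tex19.1 was 1 of 58 germline genes without a control call (Fisher's exact test, adjusted p = 0.806), Cdkn1a 1 of 29 tumour suppressors, Gata3 1 of 25 mammary epithelial genes and Rbfox3 1 of 17 neuronal genes (adjusted p = 0.537 each). Counted per library, 5 germline genes had a promoter peak in each untreated and 7, 8 and 7 in the treated libraries (exact permutation, p = 0.1, the smallest possible). Gata3 and Rbfox3 had percentiles of 14.1 and 2.23 and a control peak at another transcript start. The remaining 12 lists had no member called in DAC libraries alone, and no list had one called in controls alone. The 15 promoters called in controls alone had as their first 4 by rank the histone genes Hist1h2ao and Hist1h2bq (1 region, percentile 36.6) and Hist1h2ap and Hist1h2br (1 region, 29.1), followed by Cfap97d2, AW822073, Ctf1, Vmn1r183, and Fgf21 and Fut1 (1 region, 12.6). The counts in B16F10 moved with single libraries. Leaving out DAC replicate 1 gave 3134 DAC-alone regions and 101 DAC-alone promoters, leaving out DAC replicate 3 gave 3097 and 85, and leaving out control replicate 1 gave 76 such promoters. Leaving out any 1 of the 6 libraries gave 1075 to 1527 control-alone regions, and 26 to 34 control-alone promoters for each library except DAC replicate 1.

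Some promoters had a peak after DAC alone in both lines. Those of Cul4b, a ubiquitin ligase scaffold gene, Xlr3c, Ash2l, which encodes a subunit of histone methyltransferase complexes, Wscd1 and the adenylate kinase gene Ak7 were called in the 6 DAC libraries of both lines and in no control. Strength percentiles in 4T1 were 76.0 for Cul4b and 72.8 for Ash2l. Xlr3c and Wscd1 lacked a control peak at every annotated transcript start in both lines. Among the 8682 promoters that no control of either line called, the lines had 15 and 791 DAC-alone promoters and shared 6, against 1.37 expected (odds ratio 6.69, Fisher's exact test, p = 0.00137). That comparison was chosen after the values were seen. Over regions called in any library, which is the comparison chosen beforehand, 101 were shared among 891 and 16762 in 50486 regions, below the 295.8 expected (odds ratio 0.253, Fisher's exact test, p = 1.6e-52). For control-alone regions 23 were shared and 106.4 expected (odds ratio 0.174, Fisher's exact test, p = 2.5e-26). Both odds ratios lie below 1 partly by construction, since a region that entered the comparison was called in at least 1 library of some line. Gene by gene over both lines, 0 of 4797 genes that varied passed an adjusted p of 0.05 (exact permutation, smallest adjusted p 0.464). Of them, 16 had an unadjusted p under 0.05, and 0 members of any of the 17 lists passed when adjusted over the list alone. These zeros carry little weight, since the smallest p is 0.005 and a gene that changed in 1 line alone cannot go below 0.10 in this exact test.

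Some motif shares moved in opposite directions in the 2 lines after treatment. The test of the difference relabels treatment within each line, so it asks whether neither line changed. It hardly reaches a small p where both lines move in the same direction. The AP-1 share of peaks was lower by 4.12 percentage points in treated 4T1 cells (28.6 ± 0.153% against 32.8 ± 0.137%, n = 3 each) and higher by 2.00 points in treated B16F10 cells, a difference of 6.12 points (exact two-sided permutation of treatment within the lines, p = 0.005, adjusted p = 0.0417). The number of 4T1 peaks with an AP-1 motif was not lower, at 32200 ± 1491 after DAC and 30146 ± 725.8 in untreated cells. The share was lower while the total number of peaks was higher. With the same number of peaks per library the 4T1 share was lower by 1.55 points and the difference between the lines was 3.59 (exact permutation, p = 0.005). The TEAD share was lower by 1.59 points in 4T1 and higher by 0.449 in B16F10, a difference of 2.04, and RUNX motifs were lower by 0.769 and higher by 0.0763, a difference of 0.845 (exact permutation, p = 0.005 and adjusted p = 0.0417 each). The number of 4T1 peaks with a TEAD motif was also higher, at 16413 ± 722.6 against 14901 ± 386.5. The number with a RUNX motif was lower, at 2752 ± 129.5 against 2960.7 ± 88.03. When the whole peak was searched, the RUNX share in B16F10 fell by 0.0853 points instead. CTCF sites made up a smaller share of peaks after DAC in both lines, at 3.95 ± 0.00928% against 4.87 ± 0.0149% of peaks in 4T1 and 6.80 ± 0.0752% against 7.68 ± 0.0832% in B16F10 (exact permutation over both lines, p = 0.005, adjusted p = 0.0208). In 4T1 the number of peaks with a CTCF site was similar, at 4442.3 ± 226.7 against 4485 ± 96.39. In B16F10 it was 3775.3 ± 210.6 after DAC against 3998.3 ± 173.6. With the same number of peaks per library the share differed by −0.492 points in 4T1 and by −0.584 in B16F10 (exact permutation, p = 0.2). Over both lines it differed by −0.538 (exact permutation, p = 0.01). The median CpG density of peaks was higher in both, at 1.56 ± 0.00746 against 1.29 ± 0.0114 per 100 bp in 4T1 and 1.44 ± 0.0144 against 1.35 ± 0.0244 in B16F10 (exact permutation over both lines, p = 0.005, adjusted p = 0.0208). Measured in the 200 bp around the summit, where the median moves in steps, the difference was 0 (exact permutation, p = 1). Peaks were narrower after DAC, with median widths per library of 425 ± 10.6 bp against 482 ± 4.93 bp in 4T1. In B16F10 these widths were 509 ± 7.94 bp against 528 ± 3.61 bp. Whether the higher CpG density over whole peaks follows from their width was not tested. Repeats made up 22.1 ± 0.212% of peak bases in treated and 15.1 ± 0.193% in untreated 4T1 cells, and 13.3 ± 0.273% and 13.9 ± 0.286% in B16F10 (exact permutation, both lines p = 0.095, difference p = 0.01, adjusted p = 0.0625). The recovered background density was 1.75 in both B16F10 groups but 4.19 in untreated and 5.89 in treated 4T1 libraries. Dose, line, this density and possibly sequencer varied together, so what these differences follow cannot be told apart.

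Several genes had been chosen for description whatever their values. The promoters of B2m, which encodes the light chain of MHC class I, Nlrc5, a transactivator of MHC class I genes, and Cd274, which encodes PD-L1, were called in all 12 libraries. The tumour suppressor gene Cdkn2a had no promoter peak in any of the 12. For the pyroptosis gene Gsdme and the methyltransferase gene Dnmt1 the annotated 5′ end of the gene had no peak in 12 and 11 libraries, while another annotated transcript start was called in all 12. Antigen presentation genes had promoter peaks for 16, 15 and 15 of 28 members in untreated and 18, 20 and 17 in treated B16F10 libraries, and for 26 or 27 in every 4T1 library (exact permutation over both lines, two-sided, p = 0.15, adjusted p = 0.232). Within B16F10 the exact permutation test gave p = 0.1, the smallest possible. In 4T1 each control already called 27 members, which left little room for a rise. The difference between the lines gave p = 0.05 (exact permutation, adjusted p = 0.243). Interferon and nucleic acid sensing genes had 47, 49 and 46 of 52 in untreated and 51, 51 and 50 in treated 4T1 libraries (exact permutation over both lines, p = 0.015, adjusted p = 0.051). Of the 17 lists, germline, neuronal and p53 genes passed an adjusted p of 0.05 in this count over both lines (0.0283 each). Promoter calls over all 21918 genes were also higher after DAC, at 13502, 13635 and 13362 against 12310, 12408 and 12364 in 4T1. In B16F10 they were 10948, 11132 and 10999 against 10894, 10827 and 10903. The count per list was not set against this general rise, so a pass alone does not single out a list.

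In the untreated libraries, genes of each line's own lineage were open. Of 130561 regions in the 6 controls, 13489 were called in the 3 B16F10 controls alone and 47772 in the 3 4T1 controls alone, and 25691 in all 6. Melanocyte genes were open in B16F10 alone for 10 of the 16 members without a 4T1 call, including the pigment genes Dct, Tyrp1, Mlana, Slc45a2 and Slc24a5 and the transcription factor genes Sox10 and Pax3 (odds ratio 35.6, Fisher's exact test, adjusted p = 3.8e-09). Mammary epithelial genes were open in 4T1 alone for 21 of 25, including the adhesion gene Cdh1, Epcam, the keratin gene Krt8 and the epithelial transcription factor gene Grhl2 (odds ratio 27.2, Fisher's exact test, adjusted p = 3.0e-12). Antigen presentation genes such as H2-K1, Tap1 and Psmb8 were also open in 4T1 alone, for 10 of the 11 not called in B16F10 (Fisher's exact test, adjusted p = 1.1e-06). So were 11 of 15 interferon and nucleic acid sensing genes (Fisher's exact test, adjusted p = 8.8e-06) and 8 of 18 chemokine genes (adjusted p = 0.0159), while germline genes made 2 of 58 (odds ratio 0.182, adjusted p = 0.0159). The members named here were chosen after their values were seen, and line and sequencing run cannot be told apart. With the same number of peaks per line the 4T1 controls alone called 23744 regions and the B16F10 controls alone 18757, a much smaller gap. The recovered background density was 4.19 in the 4T1 and 1.75 in the B16F10 controls, so depth is a further difference between them. The immune lists are not given here at equal numbers of peaks.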

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

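The tests of depth, of the window edge and of the splits of the libraries were chosen or written after the results they measure were seen, and the tests of differences between the lines were planned.

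A difference between the lines in the effect of DAC had an unadjusted p under 0.05 in an exact two-sided permutation test (smallest p 0.005) for 9 measures, of which 3, the AP-1, TEAD and RUNX shares, passed after adjustment. All 9 moved in opposite directions in the lines. Relabelling treatment within each line hardly reaches a small p where both move in the same direction, so it does not compare the sizes of shared effects. The share of peaks with an AP-1 motif was 6.12 percentage points higher in the effect of B16F10 than in that of 4T1, with differences of 2.04 for TEAD and 0.845 for RUNX (permutation p = 0.005 and adjusted p = 0.0417 each). With the same number of peaks from every library the AP-1 difference was 3.59. The repeat content of peaks differed by −7.54 points (permutation p = 0.01, adjusted p = 0.0625) and the share of island-like peaks by −5.39 (permutation p = 0.03, adjusted p = 0.107). The share of peaks on chromosome X fell by 0.289 points in B16F10 and rose by 0.0164 in 4T1, a difference of −0.305 (permutation p = 0.025, adjusted p = 0.104). SP/KLF motifs differed by −0.577 (permutation p = 0.02, adjusted p = 0.1) and NF-kB motifs by −0.659 (permutation p = 0.045, adjusted p = 0.141). Imprinted genes with a promoter peak went from 8 to between 20 and 22 in 4T1 and from 10 to 9 or 10 in B16F10, a difference of −13.7 (permutation p = 0.02, adjusted p = 0.243). Dose, line, recovered background density and possibly sequencer vary together here, and none of these differences was traced to any of them.

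On unplaced and patch sequences, which no comparison used, the treated 4T1 libraries listed 1147.3 ± 43.6 peaks and the untreated ones 847 ± 22.6 (SD, n = 3), a ratio of 1.36 beside the 1.22 on the assembled chromosomes. In B16F10 the untreated libraries listed 517.3 ± 13.01 such peaks and the treated ones 510, 0 and 514, so DAC replicate 2 listed none and held peaks on the assembled chromosomes alone.

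The larger number of peaks in treated 4T1 libraries and their DAC-alone regions were weighed against greater depth. The background density recovered from the lists was 1.41 times higher in the treated libraries. Among peaks of fold enrichment of at least 5 treated minus untreated was −3017, so greater depth could account for the excess of peaks of low fold enrichment. At a −log10 q of at least 5, 98847 peaks stood against 86135, which cannot weigh against depth, since that value grows with depth. At a fold enrichment of at least 10, 28094 peaks stood against 36795, and the cause of that fall was not tested. Depth alone accounts poorly for 6179 of the 17630 DAC-alone regions, which had a fold enrichment of at least 5 in all 3 DAC libraries, because a peak that strong was within reach of the controls, where 24.3% to 27.2% of peaks were weaker, and yet 10.7% of 57883 such regions lacked any control call, against 2.52% of 61475 regions as strong in all 3 controls that lacked any DAC call and at most 0.408% that a DAC library missed of regions as strong in the 2 others. For the other DAC-alone regions depth stays open, as do the treatment itself, the removal of dead cells and a difference between sequencing runs for all of them. The 6179 regions were not counted without the repeated 16-base sequence described under the other observations. In the treated 4T1 libraries 3028, 3131 and 3024 copies of that sequence lay inside peaks of fold enrichment of at least 5. Reads shared between near-identical copies thus also stay open for part of the 6179 regions. Of the 10 splits of the 6 libraries, 1, the real one, gave as many regions and 1 as many promoters, with 22879 against 383 regions and 1017 against 11 promoters in 4T1, and 2500 against 520 and 65 against 16 in B16F10 for the highest other split, and 10 splits are too few for a share under 0.05.

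The 10 promoters of highest rank called in the 4T1 controls alone may owe the call to the border of the promoter window, since 7 of them lay at a merged region that all 6 libraries called. Among all 92 such promoters 12 did so, and counted through merged regions 81 promoters were called in controls alone and 938 in DAC libraries alone. At the 3 others, Def8, Pik3ip1 and C1qtnf1, another annotated transcript start had a peak in all 3 DAC libraries.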

How the results depend on the processing

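The fold enrichment limit of 10, the CpG-matched lists, promoters called through merged regions, promoters as the set for the overlap of the lines and the removal of the 16-base sequence were chosen after the data were seen. Of the values that answer a comparison, 528 kept direction and call, 35 moved, 10 lost the call and 11 reversed, and of the others 635 kept both, 16 lost and 5 gained the call, 4 moved and 4 reversed. The cause of a change was not tested unless given. Many of the values that kept both could not have done otherwise, so these counts do not measure stability. Leaving out a library of either line cannot alter a value of the other line. A permutation test within a line cannot pass the threshold, so its values could not gain or lose the call. The B16F10 difference in peaks thus counted as kept when it went from 3469 to 378 at a fold enrichment of at least 5. The depth of the libraries is unknown and limits what the number of peaks can show.

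At a −log10 q of at least 5 the both-line differences were 2.27 Mb in covered length (permutation p = 0.08) and −0.610 points in promoter share (p = 0.145). With the same number of peaks per library the covered length differed by 0.446 Mb, the promoter share by 0.0443 points in B16F10, 0.389 in 4T1 and 0.217 over both, the island-like share in B16F10 by 0.0961 and the AP-1 share over both by 0.239. In the same setting the AP-1 share differed by −1.55 in 4T1, the difference between the lines was 3.59, and the CTCF share differed by −0.492 in 4T1 and −0.538 over both. Regions in 4T1 numbered 11593 (DAC alone) and 8909 (control alone) and promoters 487 and 175. Regions of untreated 4T1 alone numbered 23744 and those of untreated B16F10 alone 18757.

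At a fold enrichment of at least 5 the number of peaks differed by −3017 in 4T1 and −1320 over both lines, and length by −1.43 Mb and −0.662 Mb. In B16F10 the number differed by 378. DAC-alone regions numbered 1125 in B16F10 and 8074 in 4T1, and control-alone ones 8121 in 4T1. Promoters numbered 249 and 248 in 4T1, and control-alone ones 30 in B16F10. At a fold enrichment of at least 10 the number of peaks differed by −2754, −8700 and −5727.

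A looser rule on the number of libraries raises counts by construction, while wider or added promoter windows can add or remove calls. With 2 of 3 libraries B16F10 had 5169 and 2568 regions and 152 and 56 promoters, and 4T1 had 8728 control-alone regions and 140 promoters. With promoters of plus and minus 2500 bp B16F10 had 76 DAC-alone promoters. With every transcript start, 0 lists passed in B16F10. Whole-peak motifs gave −0.0363 for NFY and −0.0853 for RUNX in B16F10. CpG density around summits differed by 0. The median over 200 bp moves in steps and treated peaks were narrower, and what accounts for the change from whole peaks was not tested. Over promoters the overlap of the lines had an odds ratio of 6.69.

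The germline list passed the threshold in 4T1 under every setting, with 26 to 34 members called in DAC libraries alone. The neuronal list in 4T1 lost it at the stricter q, with equal numbers of peaks, at plus and minus 500 bp, with every transcript start and when matched for CpG density, and the imprinted list when matched. The interferon list in 4T1 gained it at plus and minus 500 bp, without 4T1 control 2 and when matched.

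Leaving out a library loosens the rule to 2 of 2 in its arm by construction, or to none of 2 in the other. It gave 2.88 to 4.03 Mb of covered length over both lines, with p at 0.05 or 0.06 without B16F10 control 2, DAC 2 or any 4T1 control. In B16F10 it gave differences of 2005 to 4223 peaks and 0.165 to 2.01 Mb, lowest without DAC 2 in both, and 1796 to 3134 DAC-alone regions (3134 without DAC 1, 3097 without DAC 3) and 704 to 1527 control-alone regions (1221, 1527 and 1240 without controls 1, 2 and 3, and 1082, 1409 and 1075 without DAC 1, 2 and 3). DAC-alone promoters ranged from 50 to 101 (101 without DAC 1, 85 without DAC 3, 76 without control 1) and control-alone ones from 15 to 34 (32, 26 and 28 without controls 1, 2 and 3, 34 without DAC 2, 27 without DAC 3).

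Whether the replicate numbers pair the samples is unknown. Correlations of same-numbered libraries lay between −0.00685 and 0.0121 over regions, and not every library correlated best with its own number. Correlations this small show no pairing but cannot exclude it. With a replicate block (smallest p 0.031 over both lines, 0.25 within a line) the covered length, 3.45 Mb, gave p = 0.125 in the exact permutation test, CRE and NFY over both lines 0.0625, and the differences between the lines 0.0625 for repeats and chromosome X and 0.125 for island-like peaks. The block changed no other call.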

Other observations

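The tests on the 16-base sequence and on primer binding sites were chosen only after the results they measure were seen.

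A sequence repeated across the genome marked many of the regions called in treated 4T1 libraries alone. The most frequent 16-base sequence of the DAC-alone regions, CAGATTATTTGTTTAC, lay in 3598 of 17630 of them (20.4%), in 6 of 5249 control-alone regions and in 105 of 67077 regions called in all 6 libraries. The genome held 5644 copies on the assembled chromosomes, all in soft-masked repeats. Of these, 3930, 4183 and 3901 lay inside a peak in the 3 treated 4T1 libraries, against 77, 88 and 75 in the untreated ones, 49, 78 and 52 in treated B16F10 libraries and 41, 35 and 41 in untreated ones. A strong example lay in an intron of Asic2 (chromosome 11, 81545462 to 81545831, strength percentile 91.4), where the copy reads GTAAACAAATAATCTG on the forward strand at 81545542 to 81545557. Regions with the sequence carried the CRE motif in 62.8% and the NFY motif in 94.5% of cases. Without them, CRE lay in 1.77% and NFY in 12.5% of the remaining 14032 DAC-alone regions, repeats made up 37.4% of their bases, and their median CpG density was 2.37 per 100 bp.

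On chromosome Y the treated 4T1 libraries had 151 ± 12.2 peaks and the untreated ones 55 ± 2 (SD, n = 3), and B16F10 had 25 ± 0 and 20.3 ± 0.577 (exact permutation over both lines, two-sided, p = 0.005, adjusted p = 0.0208 as a share of peaks). Of the 91744698 bp of chromosome Y, 84856465 are soft-masked repeats. The lists do not say how reads shared between repeat copies were placed, so these counts cannot show that chromosome Y itself opened. In B16F10 the paired p53 consensus lay in 2 DAC-alone regions, 0 control-alone regions and 3 of 35994 regions called in all 6 libraries (odds ratio 13.4 against the last, Fisher's exact test, adjusted p = 0.0387). The comparison of the DAC-alone with the control-alone regions did not pass. The share of all B16F10 peaks with that consensus was 0.0210 ± 0.00216% after DAC and 0.0108 ± 0.00256% without it (exact permutation, p = 0.1, the smallest possible), and in 4T1 it was 0.00713 ± 0.00244% and 0.00506 ± 0.00114% (exact permutation, p = 0.3; both lines, p = 0.015, adjusted p = 0.0417). These shares rest on few peaks per library, 11.7 ± 1.53 and 5.67 ± 1.53 in B16F10 and 8 ± 2.65 and 4.67 ± 1.155 in 4T1.

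A candidate explanation for the 16-base sequence is that it marks long terminal repeats of retroviral elements primed by tRNA-Phe, such as the intracisternal A particles of the mouse. Primer binding sites for tRNA-Phe lay near 250 of the 17630 DAC-alone regions of 4T1 and 17 of 67077 regions called in all 6 libraries (odds ratio 56.7, Fisher's exact test, adjusted p = 1.1e-145 over 20 tRNAs), and near 223 of the 3598 regions with the sequence against 27 of 14032 without it (odds ratio 34.3, p = 1.6e-123). Copies inside peaks of fold enrichment of at least 5 stood at a ratio of 75.9 between treated and untreated 4T1 libraries, for which greater depth accounts poorly. The sequence was picked from regions without a control call, so part of that ratio is built in by the choice. How many copies were open cannot be told apart from reads shared between near-identical copies, since 71% of copies lay inside a peak in treated libraries and the lists do not say how such reads were placed. No repeat annotation with family names was used, so the family stays a hypothesis, and sites for tRNAs of Ile (18 against 0 regions), Pro (odds ratio 22.8), Gly (7.62), Lys (5.08) and Gln (3.62) also passed the threshold.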
